A study of Mus musculus with 6 samples.

How the data were processed

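Messenger RNA levels were measured in the mouse B-cell line 230-238 after infection with a plasmid encoding green fluorescent protein (GFP) alone or GFP together with FOG1. FOG1 is the product of the gene Zfpm1 and a cofactor of GATA transcription factors. Each group had 3 samples, which the labels call biological replicates, and each sample was run on its own array. Per the labels' protocols, total RNA was isolated without DNase treatment, amplified with a whole-transcript kit, and the sense-strand cDNA was fragmented and biotin-labelled for an Affymetrix mouse gene array. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were infected separately, so p-values measure the spread between these samples only.

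The values are log2 signals, 1 for each of 34760 probe sets on each of the 6 arrays, as deposited by the authors. The submitters' processing notes name the affy package, with no version. Background correction, normalization between arrays and summary of probes into probe sets are not given in the sources used here. The log scale was read from the values, which ran from 3.12 to 14.07, with array medians between 6.98 and 7.04. A normalization that forces the arrays to one distribution would hide a shift shared by most genes, so each change is relative to the other probe sets of the same array. No detection call or background level was used, so for dim probe sets part of the signal can be background, and a log2 change there understates the change in RNA. The number of arrays, 3 in each group, limits the precision.

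Probe sets were named through the platform's annotation table, with symbols checked through Entrez identifiers against a table of mouse RefSeq genes of assembly GRCm38.p6, which changed 0 of them and held 19855 of the named genes. An entry with 1 gene symbol was found for 21640 probe sets, which cover 19937 genes, and with several symbols for 1321. The other 11799 had no symbol in the table used here. No gene was named from a probe set with several symbols. All probe sets entered the test, and none was filtered out.

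The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, with no block), and p-values were adjusted over all 34760 probe sets by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are given as FOG1 over GFP alone, with the moderated standard error (SE). Group values are means ± SD. For each gene of a list, the 1-symbol probe set with the highest mean level was used, and 38 gene lists were tested as sets with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists. The lists covered GATA factors and FOG1 partners, B-cell stages and signalling, markers of other blood and stromal cell types, and cell cycle, stress, immune and metabolic pathways. They hold 807 different genes, of which 727 were measured by a 1-symbol probe set, and the remainder were not analysed here. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined.

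The rule named Zfpm1 and the GATA genes Gata1, Gata2 and Gata3 in every case. It then took the 12 largest rises and 12 largest falls among 1-symbol probe sets past the threshold, provided that the 3 arrays of one group all lay on one side of the other 3 and that the higher group mean reached the median of all values, 7.00. Each gene was taken once, at the most changed of its probe sets that met these conditions, and 1 predicted gene was replaced by the next. For each list described, the rule added up to 4 members with the smallest unadjusted p.

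The fit was tested on simulated data with the real means and spreads, in 10 runs of 34760 probe sets each, of which 200 were changed. Past the same threshold, it recovered 53.6% of changes of 1.41-fold, 87.5% of 2-fold changes and 98.8% of 4-fold changes, and 5.94% of its calls were unchanged probe sets. A list of 40 genes shifted by 0.2 log2 units was called in 10 of 10 runs, and 1 of 200 unshifted lists was called. That shift was larger than any list median in the real data, and the noise was drawn independently for each probe set. The list result therefore does not cover smaller shifts or genes that vary together.

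The alternatives were quantile normalization, centring each array on its median, leaving out the dimmer probe sets, testing only 1-symbol probe sets, the replicate number as a block, a variance trend with robust estimation, array weights, leaving out each array in turn, an added 2-fold minimum, an adjusted p under 0.01, and limma's treat against a log2 change of 0.5. For the lists they were camera with an estimated correlation, fry, and the mean over a gene's probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.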

Results

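The 6 arrays measured RNA from the mouse B-cell line 230-238, with 3 arrays of cells carrying GFP alone and 3 of cells carrying GFP and FOG1. Cells were cultured for 3 days after infection, sorted for GFP fluorescence and cultured for another 4 days before RNA was isolated. The comparison asks which transcripts differ when these B cells are given FOG1, a cofactor through which GATA factors repress or activate genes in blood lineages. Over all probe sets, any pair of arrays correlated at 0.9925 to 0.9960. The first principal component held 36.8% of the variance and placed the GFP-alone arrays between -16.1 and -11.4. FOG1 replicates 2 and 3 lay at 17.0 and 24.3, and FOG1 replicate 1 lay at 1.15, nearest to the GFP-alone arrays.

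Zfpm1, the gene of FOG1, rose 1.67-fold in the FOG1 cells, from 9.44 ± 0.04 to 10.18 ± 0.03 log2 units (SD, n = 3 per group; log2 change 0.74, SE 0.045; limma with Benjamini-Hochberg, adjusted p = 0.0038). Its values were 9.41, 9.49 and 9.43 on the GFP-alone arrays and 10.21, 10.16 and 10.17 on the FOG1 arrays, so each array went with its label. In GFP-alone cells its signal already lay at percentile 83.8 of all probe sets, so the contrast is a gain on a high starting signal. The largest rise of a named gene was that of Rgs18, a regulator of G protein signalling known from platelets and megakaryocytes, which rose 8.36-fold, from a mean of 5.94 ± 0.21 to values of 8.81, 9.07 and 9.12 on the FOG1 arrays (limma adjusted p = 0.00065). The largest fall was that of BC018473, a locus named after a cDNA clone, which was 13.0-fold lower with FOG1, at 6.13 ± 0.09 against 9.83 ± 0.02 (limma adjusted p = 5.0e-06). Gdpd3, a phosphodiesterase of lysophospholipids, was 4.42-fold lower (limma adjusted p = 0.00065), and the sialyltransferase gene St6galnac2 was 2.84-fold lower (limma adjusted p = 0.00016).

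**Figure D1:**
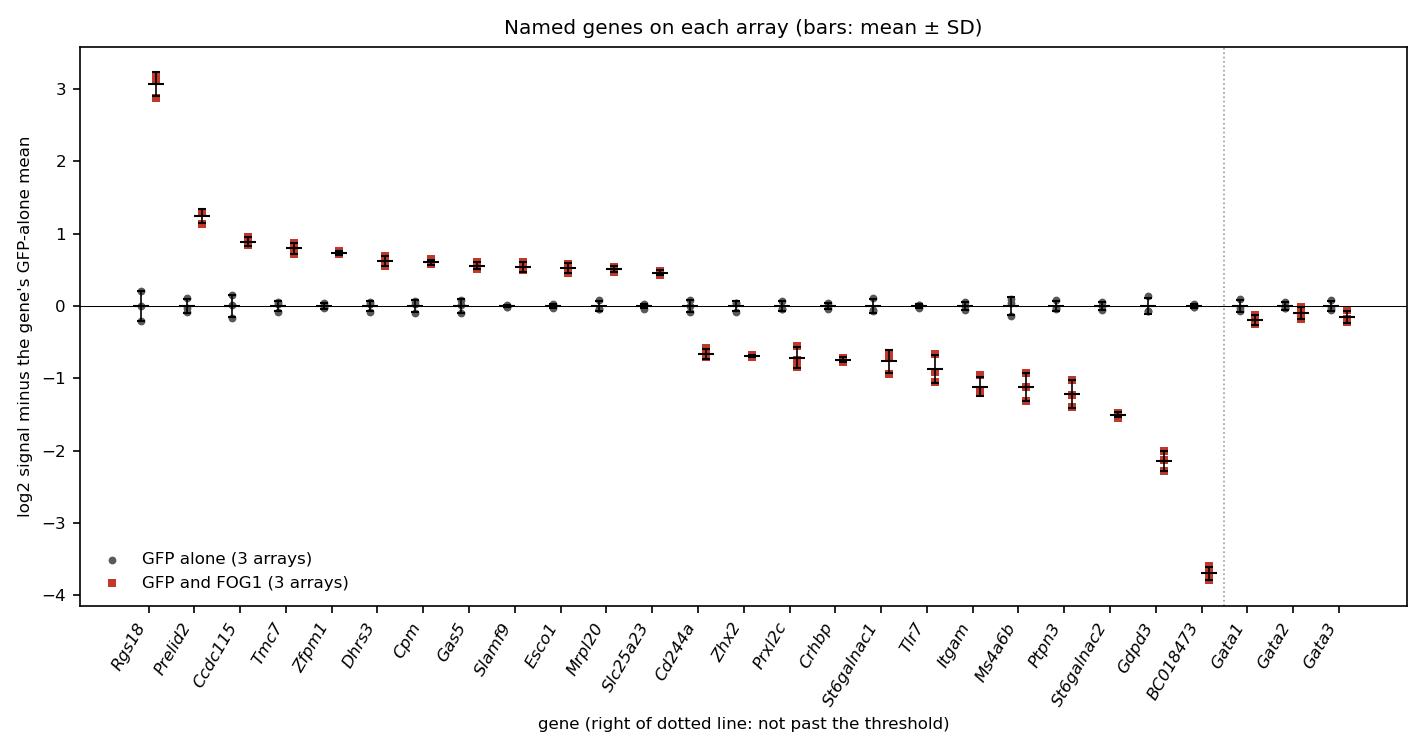
Log2 signal of each named gene on each of the 6 arrays, shown relative to the gene's GFP-alone mean (grey circles, GFP alone; red squares, GFP and FOG1; black bars, mean ± SD of 3 arrays). Rgs18 lies at 3.06 and BC018473 at -3.70, while Gata1, Gata2 and Gata3, right of the dotted line, lie between -0.20 and -0.10 and did not pass the threshold.

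The other genes that rose did so by smaller amounts. Prelid2 rose 2.37-fold (log2 change 1.24, SE 0.073; limma adjusted p = 0.0036). Ccdc115, which takes part in assembly of the vacuolar proton pump, rose 1.85-fold and Tmc7, of the transmembrane channel-like family, 1.74-fold. Dhrs3, a reductase of retinaldehyde, rose 1.53-fold and Cpm, the membrane-bound carboxypeptidase M, 1.52-fold. Gas5, a noncoding host transcript of small nucleolar RNAs, rose 1.47-fold at 1 of its 4 probe sets, and the other 3 had positive log2 changes of 0.18 to 0.68 that did not pass. Slamf9, a receptor of the SLAM family, rose 1.45-fold. Esco1, an acetyltransferase of cohesin, rose 1.43-fold at 1 of its 2 probe sets, with a log2 change of 0.27 at the other. Mrpl20, of the mitochondrial ribosome, rose 1.43-fold and Slc25a23, a mitochondrial carrier, 1.38-fold. From Ccdc115 to Slc25a23 the limma adjusted p lay between 0.0106 (Tmc7) and 0.038 (Gas5).

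The other named genes that fell were 1.58-fold to 2.32-fold lower with FOG1. Itgam, the alpha M integrin chain known from myeloid cells, was 2.16-fold lower with FOG1, at 6.96 ± 0.13 against 8.07 ± 0.06 (limma adjusted p = 0.0075). Tlr7, an endosomal receptor for single-stranded RNA, was 1.83-fold lower. Ms4a6b, a membrane protein of the MS4A family, was 2.18-fold lower, and Cd244a, a SLAM family receptor known from natural killer cells, was 1.58-fold lower. St6galnac1, a sialyltransferase related to St6galnac2, was 1.70-fold lower. The protein tyrosine phosphatase gene Ptpn3 was 2.32-fold lower, and 7 of its 12 probe sets passed, while the other 5 had log2 changes of -0.52 to -0.34. Crhbp, which binds corticotropin-releasing hormone, fell from 10.85 ± 0.05 to 10.10 ± 0.03, or 1.67-fold (limma adjusted p = 0.0048). Zhx2, a zinc finger and homeobox repressor of transcription, was 1.61-fold lower (limma adjusted p = 0.0099), and Prxl2c, a peroxiredoxin-like gene, 1.64-fold lower. For Tlr7, Ms4a6b, Cd244a, St6galnac1, Ptpn3 and Prxl2c the limma adjusted p lay between 0.014 (Ptpn3) and 0.048 (St6galnac1).

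In all, 78 of 34760 probe sets passed the threshold, of which 36 rose and 42 fell, and 4342 had an unadjusted p under 0.05 (limma). Among 1-symbol probe sets, 13 rose and 28 fell, and they stand for 13 genes that rose and 21 that fell. A change of at least 2-fold was reached by 12 of the probe sets that rose and 11 of those that fell. Among probe sets without a symbol here, 21 rose and 8 fell, and 4 of the 5 largest rises belong to them. The largest of these rose 56.5-fold, from 5.37 ± 0.15 to 11.19 ± 0.34, and the next 8.21-fold, from 8.56 ± 0.03 to 11.60 ± 0.05. All 78 called probe sets had groups that did not overlap, as did 6807 probe sets in all (19.6%, where chance gives 10%). Leaving out 1 array reduced the count to 20, 21 and 21 without GFP-alone replicates 1, 2 and 3 and to 38, 17 and 28 without FOG1 replicates 1, 2 and 3. Of the 24 changed genes named above, 7 passed whichever single array was left out, namely Zfpm1, Rgs18, Prelid2, BC018473, Gdpd3, St6galnac2 and Crhbp.

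**Figure D2:**
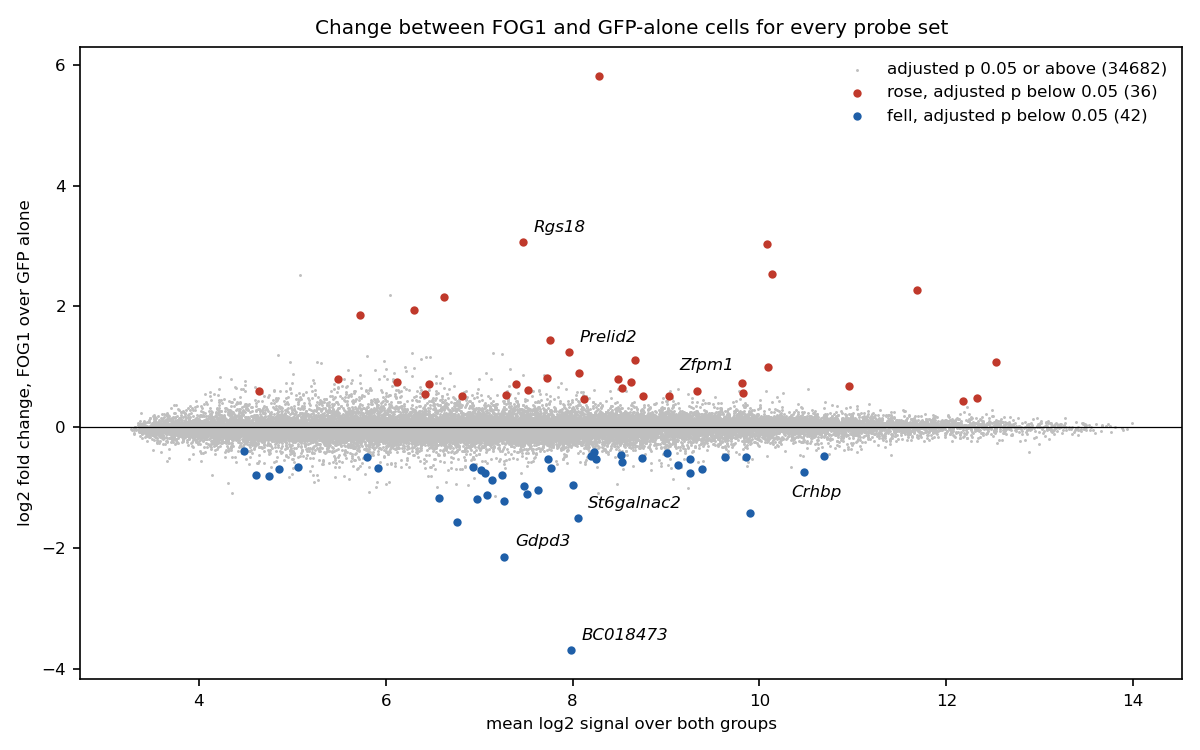
Log2 fold change of FOG1 over GFP alone (vertical axis) against the mean log2 signal of both groups (horizontal axis), with 1 point per probe set (red, 36 that rose; blue, 42 that fell; grey, not past the threshold). The highest point, at 5.82, has no gene symbol here, and BC018473 is the lowest at -3.70.

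The GATA factors that FOG1 partners did not pass the threshold. In GFP-alone cells the signals of Gata1, Gata2 and Gata3 lay at percentiles 45.5, 47.0 and 35.0 of all probe sets, below the median signal level. Part of such signals can be background, so changes of these genes could be understated. Gata1 had a log2 change of -0.20 (SE 0.064; limma adjusted p = 0.32), Gata2 of -0.10 (adjusted p = 0.53) and Gata3 of -0.15 (adjusted p = 0.41). None of the 20 measured members of the list of GATA factors and haematopoietic partners passed, over all probe sets or adjusted over the list alone, and the list's median log2 change was -0.03 (limma's camera, adjusted p = 0.36). Lmo2, a bridging factor of GATA complexes, had a log2 change of -0.19. The 15 measured genes of the repressor complexes that bind FOG1, NuRD and CtBP, had a median of 0.04 and none passed (camera adjusted p = 0.055). Its members with the smallest p included the histone deacetylase genes Hdac1 and Hdac2, both at 0.15.

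Cell cycle genes were slightly higher as groups in the FOG1 cells at camera's preset correlation, but none of these calls held with an estimated one. All 29 measured genes of the G2 and mitosis list had positive log2 changes, with a median of 0.11 (camera adjusted p = 8.2e-11, and adjusted p = 0.55 with an estimated correlation). Of 29 S phase and DNA replication genes, 27 were positive, with a median of 0.10 (adjusted p = 5.1e-09, and adjusted p = 0.55 with an estimated correlation). No single member passed over all probe sets, while 3 and 4 did when adjusted over the list alone. Members with the smallest p were the spindle checkpoint gene Bub1b (0.21) and the spindle gene Prc1 (0.24) for mitosis, and the helicase subunit gene Mcm3 (0.26) and the cyclin gene Ccne2 (0.27) for S phase. Replication-dependent histone genes had a median of 0.10 over 11 genes, with H2ac4 at 0.24 (adjusted p = 0.0050, and adjusted p = 0.55 with an estimated correlation). Cell cycle inhibitors and D cyclins had a median of 0.07 over 15 genes (adjusted p = 0.020, and adjusted p = 0.55 with an estimated correlation). Their smallest p values belonged to the inhibitor gene Rbl1 (0.19) and the cyclin gene Ccnd3 (0.18). The call of this mixed list was also lost under quantile normalization (adjusted p = 0.074), without dim probe sets (0.078) and without FOG1 replicate 1 (0.053). Ribosome biogenesis and MYC targets had a median of 0.04 over 30 genes, with the purine synthesis gene Ppat at 0.26 (adjusted p = 0.0037, and adjusted p = 0.59 with an estimated correlation). That median was inside the range of random lists of like signal level, -0.002 to 0.060, and the call was lost under quantile normalization (median 0.02, adjusted p = 0.084). It was 0.06 without GFP-alone replicate 2, 0.07 without FOG1 replicate 1 and 0.06 after median centring. Adjusted over the list alone, 1 histone gene passed, and none did on the ribosome list or the list of inhibitors and D cyclins.

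Genes of mature B cells and of immune activation were slightly lower as groups at the preset correlation, and these calls too were lost with an estimated one. The 23 measured mature B-cell markers had a median log2 change of -0.13 (camera adjusted p = 9.8e-04, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone, 7 of them fell and 1 rose, while none passed over all probe sets. Those with the smallest p were the IgE receptor gene Fcer2a (-0.45), the IgM receptor gene Fcmr (-0.31), Ms4a1, which encodes the surface marker CD20 (-0.34), and the adaptor gene Bank1 (-0.30). Irf4, which encodes a transcription factor of activated B cells and plasma cells, was the member that rose, by 0.19. MHC class II genes had a median of -0.06 over 11 genes (adjusted p = 0.021, and adjusted p = 0.59 with an estimated correlation), with H2-Ob at -0.23, which passed over the list alone. Their call was lost without GFP-alone replicate 1 and without FOG1 replicate 1 (adjusted p = 0.15 each), and their median was -0.04 after median centring. NF-kB targets and components had a median of -0.10 over 24 genes (adjusted p = 0.0050, and adjusted p = 0.59 with an estimated correlation), with the chemokine gene Ccl3 at -0.69 and none passing over the list alone. Without FOG1 replicate 3 their median was -0.06 (adjusted p = 0.028). Immediate-early genes had a median of -0.10 over 30 genes (adjusted p = 0.018, and adjusted p = 0.70 with an estimated correlation). Over the list alone the activation marker gene Cd69 passed at -0.25 and Dusp6 in the other direction at 0.30. This call was lost without GFP-alone replicate 2 (median -0.06, adjusted p = 0.15) and without FOG1 replicate 3 (median -0.03, adjusted p = 0.44).

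The list of early B-cell identity was not shifted past the threshold, with a median of 0.01 over 29 pro-B and pre-B genes (camera adjusted p = 0.19). Its strongest member was Cd79a, a signalling chain of the B-cell receptor, at -0.41, which passed over the list alone but not over all probe sets (limma adjusted p = 0.088). The interleukin 7 receptor gene Il7r was at 0.20. The B-cell receptor signalling list, which shares Cd79a, had a median of -0.02 over 23 genes (camera adjusted p = 0.38).

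Listed markers of blood lineages whose development FOG1 is known to influence did not pass. Rgs18, known from platelets and megakaryocytes, rose 8.36-fold but was not on these lists. None of 21 erythroid, 19 megakaryocyte and platelet, 19 mast cell and basophil or 10 eosinophil markers passed, over all probe sets or adjusted over the list alone, and their medians were -0.01, 0.01, -0.03 and -0.04 (camera adjusted p = 0.96, 0.59, 0.35 and 0.52). Itga2b, the platelet integrin chain, had a log2 change of 0.22 (limma adjusted p = 0.29) and the transferrin receptor gene Tfrc also 0.22 (0.25). Only 6 erythroid, 9 megakaryocyte and platelet, 1 mast cell and basophil and 2 eosinophil markers reached the median signal level. Falls among the others could be hidden. The 23 monocyte and macrophage markers had a median of -0.06 (camera adjusted p = 0.019, and 0.55 with an estimated correlation), and Itgam was the only member that passed. That median was -0.12 over 9 genes without dim probe sets (adjusted p = 0.0014) and -0.04 after median centring. Besides Itgam, the smallest p values belonged to Cd14 (-0.20), Fcgr2b (-0.17) and Fcer1g (0.19). Itgam also stood on the lists of neutrophil markers and of integrins, and it was the only 1 of the 727 measured list genes that passed over all probe sets.

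**Figure D3:**
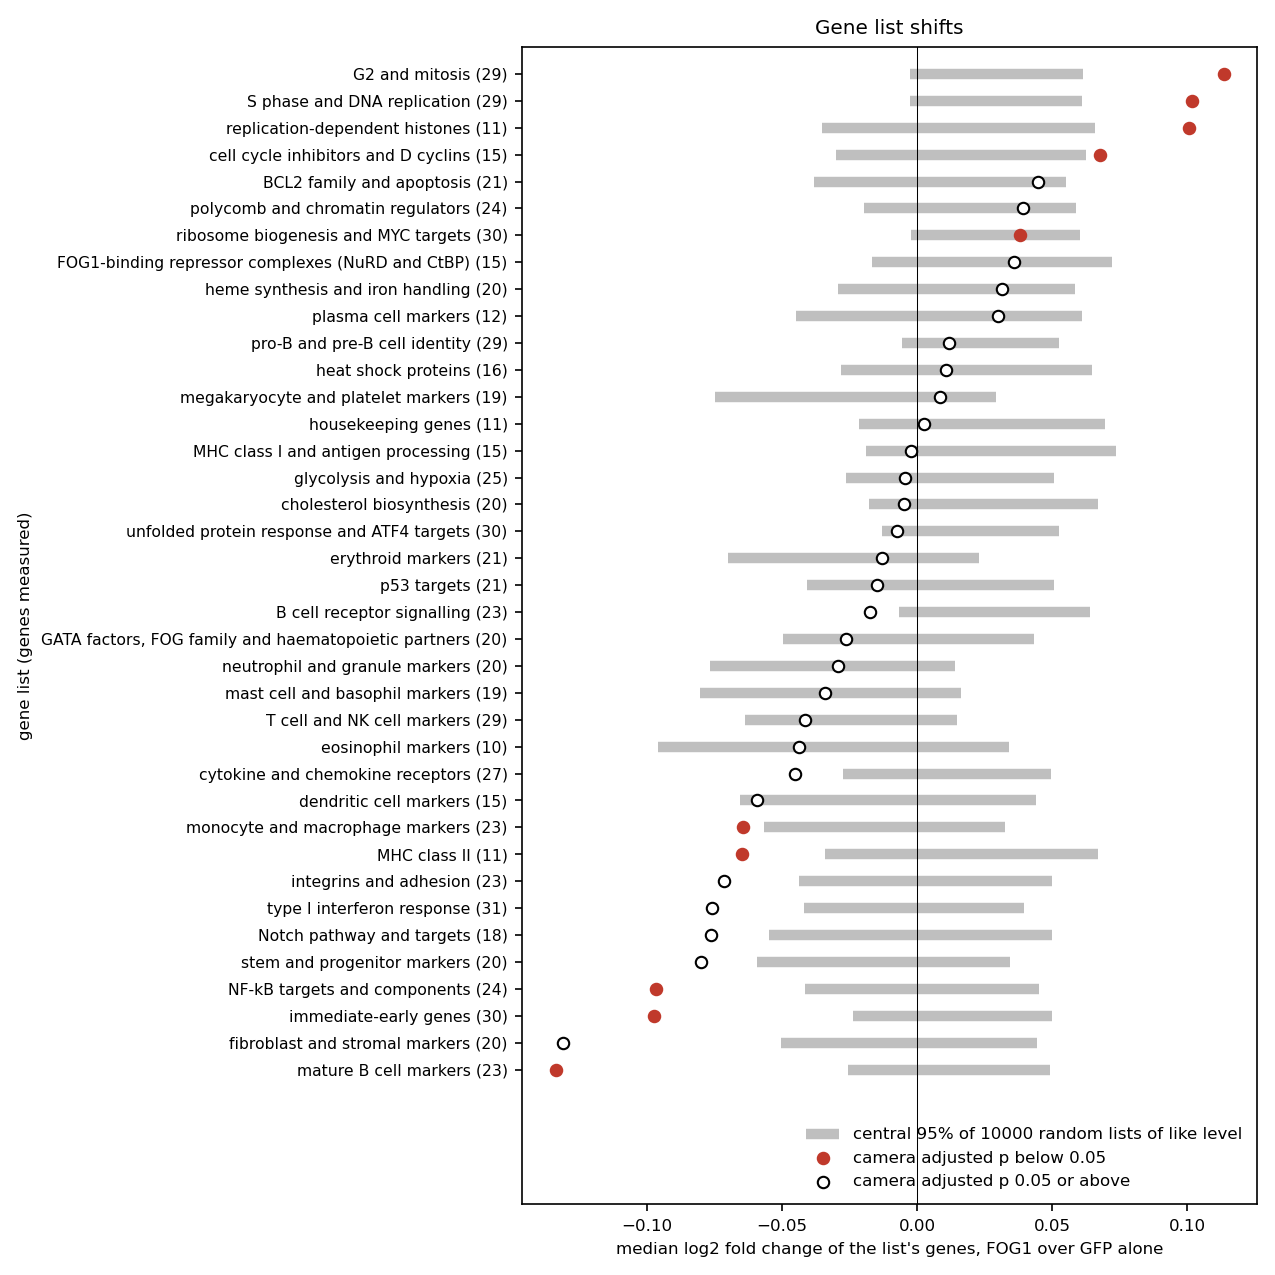
Median log2 fold change, FOG1 over GFP alone, of each of the 38 gene lists (circles; filled, camera adjusted p below 0.05 at the preset correlation; number of measured genes in parentheses). Grey bars show the central 95% of medians of 10000 random lists with the same mean levels, and the 4 cell cycle and histone lists at the top lie above their bars while 12 lists, mature B-cell markers among them, lie below theirs.

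Of the remaining cell type lists, neutrophil, dendritic cell, T and NK cell, stem and progenitor, fibroblast and plasma cell markers, none passed with camera. The fibroblast and stromal list had the lowest median of these at -0.13 over 20 genes, with Thy1 at -0.29 (camera adjusted p = 0.17). Stem and progenitor markers had a median of -0.08 (adjusted p = 0.15), with Slamf1 at -0.67 (limma adjusted p = 0.18). T and NK cell markers had a median of -0.04 (camera adjusted p = 0.055), with the B-cell and T-cell gene Cd5 at -0.32. The medians were -0.06 for dendritic cell (0.092), -0.03 for neutrophil (0.17) and 0.03 for plasma cell markers (0.72), with camera adjusted p in parentheses. Adjusted over each list alone, 4 members passed and all 4 fell, namely Itgam, Cd5, Slamf1 and the plasma cell marker Mzb1. Mzb1 had a log2 change of -0.38 and did not pass over all probe sets (limma adjusted p = 0.091).

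A further 14 lists did not pass, with camera adjusted p between 0.097 and 0.96 and medians between -0.08 and 0.04. They were the Notch pathway, p53 targets, the BCL2 family and apoptosis, the type I interferon response, MHC class I and antigen processing, cytokine and chemokine receptors, integrins and adhesion, heat shock proteins, the unfolded protein response, glycolysis and hypoxia, cholesterol biosynthesis, polycomb and chromatin regulators, heme synthesis and iron handling, and housekeeping genes. Adjusted over each list alone, 10 of their 302 entries passed, 5 in each direction. Those included Hes1, a Notch target, at -0.34, Stard4, a cholesterol carrier gene, at 0.37 and the polycomb gene Rnf2 at 0.33.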

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

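The count of 78 probe sets was 73 after quantile normalization, 64 after median centring, 94 without dim probe sets, 116 with a variance trend and 87 with array weights, all within 1.5 times. Testing 1-symbol probe sets alone gave 102 (37 rose, 65 fell), against 41 of the same probe sets (13 and 28) when all were tested, with 41 shared. By construction it was lower with stricter criteria, at 23 with a 2-fold minimum, 20 at an adjusted p under 0.01 and 10 with treat. Without 1 array it ranged from 17 to 38, and fewer samples are one reason. Zfpm1 kept its rise past the threshold in each of these settings run for it, at 0.72 to 0.76. Of the 24 named genes that changed, Gas5, St6galnac1 and Prxl2c missed the threshold after quantile normalization, and these and Tlr7 after median centring (adjusted p = 0.053 to 0.068), and no direction turned. The 10 lists became 16 without dim probe sets, 0 with an estimated correlation and 0 with fry, with 2 and 11 lists at an unadjusted p under 0.05 (camera and fry), and 9 to 13 without 1 array. Same-numbered arrays did not deviate together (correlations -0.07, 0.01 and -0.04), and 0 of 6 arrays correlated best with its own number, so the numbers were not taken to pair the samples. With the replicate block, 9 probe sets and 11 lists passed. Of the 24 named genes only 4 passed there, namely Rgs18, BC018473, Gdpd3 and St6galnac2, and the other 20 missed the threshold. Zfpm1 (0.74) had a limma adjusted p of 0.097 with the block (0.00071 to 0.043 elsewhere). The cause of the moves in list counts was not tested, but a higher correlation cannot be the reason for every lost call. For the histone and the monocyte and macrophage lists the estimated correlations, 0.009 and 0.006, were below the preset 0.01. Their unadjusted camera p was 0.00074 and 0.0041 at the preset, and 0.027 and 0.041 with the estimates. A pseudocount was not run because the values are already on the log2 scale. Signal over background was not analysed here, so changes of dim genes may be understated.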

Other observations

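Some gene families of the changed genes were looked up after their values had been seen. Of 9 measured SLAM family genes, Slamf9 rose and Cd244a fell, while Slamf1 (-0.67, limma adjusted p = 0.18), Cd84 (0.32, 0.25), Ly9 (0.27, 0.16), Cd48 (0.24, 0.20) and Slamf7 (0.23, 0.22) did not pass. Of 19 MS4A genes, Ms4a6b fell, and Ms4a4c (-0.50, limma adjusted p = 0.25) and Ms4a1 (-0.34, 0.16) did not pass. Of 20 Rgs genes, Rgs18 rose, and the log2 changes of the others lay between -0.16 and 0.08. Further genes past the threshold, outside the naming rule, included the growth factor gene Tgfb3 (-0.63), the nuclease gene Dnase1l3 (-0.53), Samd9l (-0.50), Pcp4 (-0.50), the kinesin gene Kif21b (-0.50), the adhesion gene Pcdh9 (-0.42) and the formin gene Fmn2 (0.72).

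The tests below were chosen after the results were seen, except the splits of the 6 arrays for the 2 counts, which were planned. The arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. For probe sets, 1 of the 10 splits, the real one, gave as many as 78, and the highest of the others gave 0. For gene lists, 2 of the 10 gave at least the real 10, and the highest other gave 13, with GFP-alone replicate 1 and FOG1 replicate 1 exchanged.

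St6galnac2, BC018473 and St6galnac1, which all fell, follow one another among the measured genes in the gene order of assembly GRCm38.p6. As many as 2 adjacent pairs came up in a share of 0.0021 of 10000 random draws of 34 genes, but those pairs prompted the count, and without St6galnac1, whose call was lost in 9 of 13 settings (log2 changes -0.82 to -0.68), 1 pair is left (a share of 0.048), so chance adjacency stays open. A loss that takes in most of the 5 measured genes on each side is argued against by their median log2 change of 0.015 (bootstrap SE 0.034), against a bound of -0.3. The nearest genes, Snhg16 (-0.21, SE 0.091) and Mxra7 (-0.16, SE 0.19), had the largest falls of the 10. The median cannot see a loss that ends close to the trio, so that stays open. Signal shared across the whole sialyltransferase family is argued against by the 6 other St6gal and St6galnac genes, with a median of -0.021 (SE 0.029), while signal shared by St6galnac1 and St6galnac2 alone stays open. An effect of FOG1, read-through between the neighbours and a difference between the infected populations stay open and were not tested.

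The medians of the cell cycle and mature B-cell lists, whose camera calls were lost with an estimated correlation (adjusted p = 0.55 and 0.59) and under fry (0.090 to 0.099), were set against the trend of change with signal level. Among 10000 random lists of like mean level, the G2 and mitosis list (0.11) and the S phase list (0.10) each lay at percentile 100, and the mature B-cell list (-0.13) at percentile 0, so this trend is argued against as the whole of each shift. Of the 38 lists, 4 lay above and 12 below their matched ranges, the uncalled fibroblast list (-0.13) among them, and of the called lists the ribosome list lay inside, so lying outside is not particular to these lists. Variation between arrays shared by a list's genes stays open: only the real split of the 10 gave a G2 median as large, 1 of 10, with 0.07 as the highest other, and 10 splits are too few to decide. A difference in growth between the cultures could give the same picture as an effect of FOG1 and was not tested.

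The fall of Itgam raises the question of fewer monocytes or macrophages among the FOG1 cells, although the cells are a sorted line. Of the 22 other members of the monocyte and macrophage list, 18 had negative log2 changes, with a median of -0.06, and the largest fall was -0.20 (Cd14, SE 0.054), against -1.11 for Itgam. Fcer1g had a positive change (0.19, SE 0.048). Only 8 of the 22 reached the median signal level, so most could hide a fall, and the test was set after the values had been seen. The explanation therefore stays open, as does a change of Itgam within the B cells.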
